A study of Mus musculus with 12 samples.

How the data were processed

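The series holds 12 samples of primary mouse T cells on a C57BL/6 background, of a wild-type (WT) or an LDHA-KO genotype. LDHA is lactate dehydrogenase A, the enzyme that turns pyruvate into lactate at the end of glycolysis. Per the labels' protocols, naive CD4 T cells were activated with plate-bound anti-CD3 at 5 µg/ml and anti-CD28 at 2 µg/ml, and kept under Th1-polarising conditions for 3 days. The medium held IL-2 at 100 U/ml, anti-IL-4 at 10 µg/ml and IL-12 at 10 ng/ml. For RNA, per the labels' protocols, the cells were then restimulated for 4 h with PMA at 50 ng/ml and ionomycin at 1 µM, with GolgiStop, a blocker of protein secretion. Total RNA was extracted and libraries were made with Illumina's standard protocols, per the labels' protocols. The RNA part has 4 libraries, 2 per genotype. The other 8 samples, 4 of chromatin immunoprecipitated for acetylated histone H3K9 and 4 of input, were not analysed here.

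The values used were the counts of reads per gene that the authors deposited as a single table, not normalised, with Ensembl gene IDs. Whole numbers and differing library totals were checked in the values. The table's columns name the genotype and a number but no assay; they were taken as the RNA libraries because the values are counts per gene. Per the submitters' processing notes, the tools named for the series were Trimmomatic 0.33, FastQC 0.11.2, STAR 2.3.0e, Bowtie2 2.2.6 and HTSeq 0.6.0, with the genome build mm10 (GRCm38); the notes as used here give no role or order of these tools. The annotation release, the strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. How reads over overlapping genes were assigned is therefore open, and counts of overlapping genes, antisense genes and genes with near-identical copies are uncertain. Overlaps are named below for some genes only, so a gene given without an overlap may still have one. If the strand opposite to the library's was counted, the counts of all genes, also of those that overlap no other, would be of antisense reads.

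The table had 43374 rows for 39179 IDs. The 1557 repeated IDs had identical values on each of their rows, and 4195 extra rows were removed. Of the IDs, 37607 had a gene symbol in the Ensembl table used, and 18659 had a count in at least 1 library. IDs with no symbol held 2.04% to 2.78% of a library's counts. Positions and overlaps came from RefSeq on GRCm38.p6, matched by symbol, which placed 9159 of the tested genes; 4609 of these overlapped another RefSeq gene by at least 1 bp on either strand and 4550 overlapped none.

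Library totals were 1293178 and 1245903 counts in WT and 919741 and 1192304 in LDHA-KO. A single count was worth 0.773 to 1.09 CPM (counts scaled by the library total), and a count of 0 allowed up to 3 counts, or 2.32 to 3.26 CPM. Intervals and this limit cover counting error only. Replicates of a genotype were compared by a chi-square test over genes with at least 10 summed counts. The statistic per gene was 1.15 in WT and 1.23 in LDHA-KO, where counting noise alone gives 1, and it was 2.61 and 5.76 over genes with at least 1000 summed counts. Most genes compared had 10 to under 200 summed counts (8496 of 11377 in WT, 8540 of 10808 in LDHA-KO). Over these the statistic was 1.05 and 1.04, close to counting noise (chi-square p = 0.000511 and 0.0046). Both pairs differed by more than counting noise, mainly in abundant genes, and were kept as 2 replicates each. Nothing in the labels says that the libraries of a genotype came from separate animals or cultures, so p-values measure only the spread between these libraries, which may be technical. Equal replicate numbers are shared between genotypes in the labels, with nothing said of a shared animal or day, so the numbers were not used as pairs.

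Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F-test with TMM scaling and genotype as the single factor. The default expression filter (minimum count 10, minimum total 15) left 9914 genes, of which 9810 had a symbol. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. Standard errors (SE) of log2 fold changes were derived from the F statistic. CPM values are TMM-scaled and given as mean ± SD. The common dispersion was 0.00163, a biological coefficient of variation of 4.03%. Adjusted p-values given for genes are edgeR's throughout, unless another tool is named.

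Gene lists were tested with camera from limma 3.58.1, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over 25 lists. The 28 lists covered T helper states, activation, metabolism, stress, proliferation, translation, interferon response, other cell types and RNA selection. Of their 890 entries, 881 were matched to an ID; 3 lists had too few tested members, with at least 3 required. Adjusted p-values given for lists are camera's. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera uses only the few residual degrees of freedom that 4 libraries leave. A call is then hard to reach for any list, so a call lost there cannot decide about a list.

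The design, the lists, the rule for named genes and all alternatives but the last pair below were fixed before the data were examined. The rule named Ldha and Ifng; the 10 largest fitted fold changes in each direction among called genes with a mean log2 CPM of at least 3 and no overlap between the groups, leaving out unnamed gene models, Rik clones and pseudogenes named as such; up to 4 members of each described list with the smallest adjusted p; and a fixed panel of Tbx21, Stat4, Il12rb2, Cxcr3, Tnf, Il2, Gzmb, Ldhb, Myc, Hif1a and Acly. Results for some of the genes that this rule names, and a test that needed such a gene, are not reported here. Alternatives were RLE scaling, library totals alone, no filter on low counts, a filter of CPM above 1 in 2 libraries, DESeq2 1.42.0, limma-voom, a replicate block, each library left out in turn, a minimum 2-fold change, and for lists the estimated correlation and fry. Genes that overlap no other RefSeq gene (GenomicRanges 1.54.1) and libraries thinned to the smallest total were alternatives chosen after seeing the data. A correction for GC content and gene length was planned and not run, because no genome sequence or transcript length was used here. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

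The steps were tested on simulated data drawn from the means, library sizes and edgeR's trended dispersion of the comparison of LDHA-KO with WT. Genes were drawn independently, and 9626 passed the filter. Of 96 genes changed 1.5-fold, 36.5% were recovered, and of 97 genes changed 2-fold, 72.2%. There were 7 calls among unchanged genes, 5.98% of all calls. A list made to fall was called, and 0 of 24 random lists were. These shares hold only for the spread that edgeR fitted and for genes that do not vary together.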

Results

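Gene expression was measured by RNA sequencing in mouse Th1 cells, the helper T cells that make interferon-gamma, from 2 WT and 2 LDHA-KO libraries. Cells had been polarised for 3 days and restimulated with PMA and ionomycin for 4 h. The comparison asks how loss of lactate dehydrogenase A changes the transcripts of these cells; the series title names aerobic glycolysis and Th1 differentiation as its subject. Library totals ranged from 919741 to 1293178 counts over genes, a low depth at which a single count is about 1 CPM. The 10 most abundant genes took 5.94% and 5.95% of the counts in WT and 7.39% and 7.79% in LDHA-KO. Pearson's r of log CPM, computed across genes, which are not independent replicates, was 0.979 between the WT libraries, 0.972 between the LDHA-KO libraries and 0.923 to 0.928 between genotypes.

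Ldha, the targeted gene (ENSMUSG00000063229; chromosome 7, 46842274 to 46855627, GRCm38.p6), had 1055 and 1006 counts in the WT libraries and 42 and 53 in the LDHA-KO libraries. Its level was 801 ± 8.31 CPM in WT and 47.1 ± 0.577 CPM in LDHA-KO (SD, n = 2 each), a fall of 17.0-fold (log2 fold change -4.09, SE 0.11, edgeR adjusted p = 2.19e-30). Both LDHA-KO libraries thus matched their label. Ldhb, which encodes the other common lactate dehydrogenase subunit, held 3 to 7 counts per library and was too low to be tested. Ifng, the gene for interferon-gamma (ENSMUSG00000055170; chromosome 10, 118441046 to 118445894), fell from 1583 ± 3.89 CPM to 384 ± 3.13 CPM (SD, n = 2 each; log2 fold change -2.04, SE 0.06, edgeR adjusted p = 2.46e-27). Ldha overlaps the gene model Gm39011, and Ifng overlaps no other RefSeq gene.

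**Figure D1:**
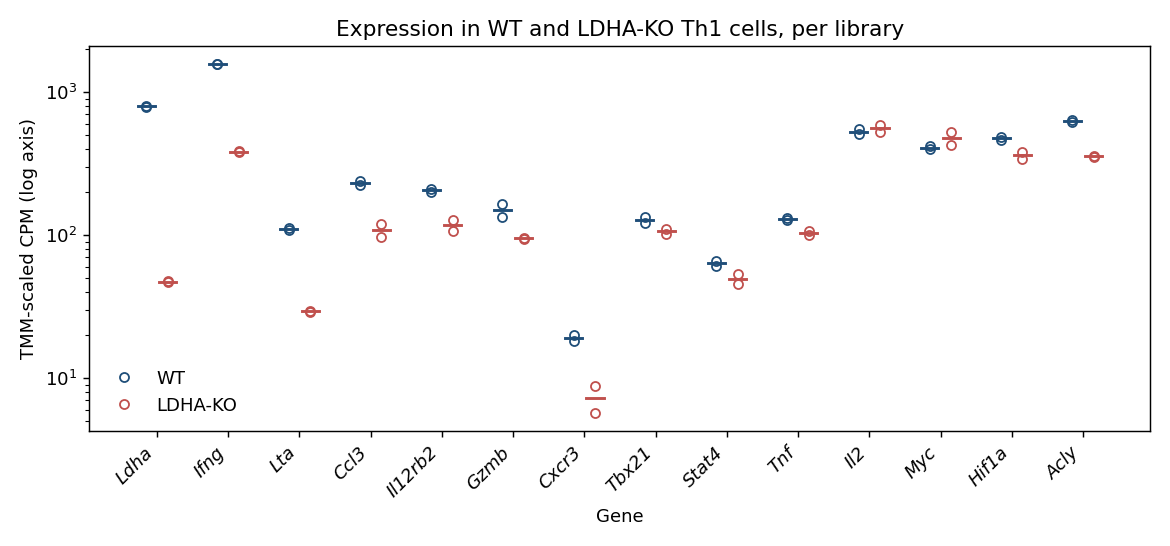
TMM-scaled CPM on a log axis for Ldha, Ifng and other genes named in the text, with a circle for each of the 4 libraries and a bar for the mean of each genotype. Ldha lies near 801 CPM in WT and 47.1 CPM in LDHA-KO, Ifng near 1583 and 384 CPM, and the Il2 circles of both genotypes overlap.

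Between LDHA-KO and WT, 3076 of 9914 tested genes differed at an adjusted p under 0.05, 1549 higher and 1527 lower in LDHA-KO. Changes of at least 2-fold numbered 335 higher and 507 lower. After Ldha, the largest fitted falls were in Mx2 (-3.56), an interferon-induced gene listed as a transcribed pseudogene in the reference, Galnt5 (-3.42), the cytokine gene Il24 (-3.22), Tmem204 (-3.03), the antiviral gene Oas3 (-2.95), F3 (-2.93), which encodes tissue factor, Mirt1 (-2.93), the stress response gene Nupr1 (-2.83) and Dhx58 (-2.80), an RNA helicase gene of antiviral sensing; all values are log2 fold changes. The largest rises included Fxyd3 (3.98), Dnah7a (3.90), Thbs1 (3.89), which encodes thrombospondin 1, BC106179 (3.69), P2rx5 (3.35), Apc2 (3.30), Fscn1 (3.29), Tbc1d4 (3.27) and Cecr2 (3.26). Fscn1, which encodes the actin-bundling protein fascin, went from 17.2 ± 3.70 to 169 ± 13.6 CPM (SD, n = 2 each, edgeR adjusted p = 2.00e-18).

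Most of these large changes rested on few counts in the lower genotype. With 2 summed counts in LDHA-KO against 33 in WT, the ratio of Mx2 was 13.0, with a 95% counting interval of 3.32 to 112. For 3 summed counts, the ratio was 9.95 (3.16 to 50.4) for Il24 and 8.12 (2.53 to 41.5) for F3 and Mirt1, as WT over LDHA-KO. As LDHA-KO over WT, it was 16.1 (5.12 to 81.6) for Thbs1 and 14.0 (4.39 to 71.4) for BC106179. Oas3 and Fscn1 had 19 and 44 counts in their lower genotype, and intervals of 4.87 to 13.3 and 7.15 to 13.8. F3 lost its call without LDHA-KO replicate 2 (log2 fold change -2.35), as did Mirt1 (-2.35), which also lost it without WT replicate 2 (-2.65). Without LDHA-KO replicate 1, Il24 has 0 counts left in LDHA-KO, a fall of 5.59-fold against a floor of 3 counts in that library (lower 95% counting limit 4.33). The same holds for Nupr1 without LDHA-KO replicate 2, 4.36-fold against that floor (lower limit 3.37). Without LDHA-KO replicate 2 the fitted value of Il24 was -2.08, from 3 counts, a ratio of 4.36 (1.38 to 22.1). These 2 genes were still called in each case. Mx2, Il24, Oas3, F3, Thbs1 and Fscn1 overlap no other RefSeq gene. The other genes named above for large changes do, among them Tmem204 (Ift140), Fxyd3 (Lgi4) and BC106179 (St6gal1), the rest with gene models or a Rik clone, so their counts are uncertain.

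**Figure D2:**
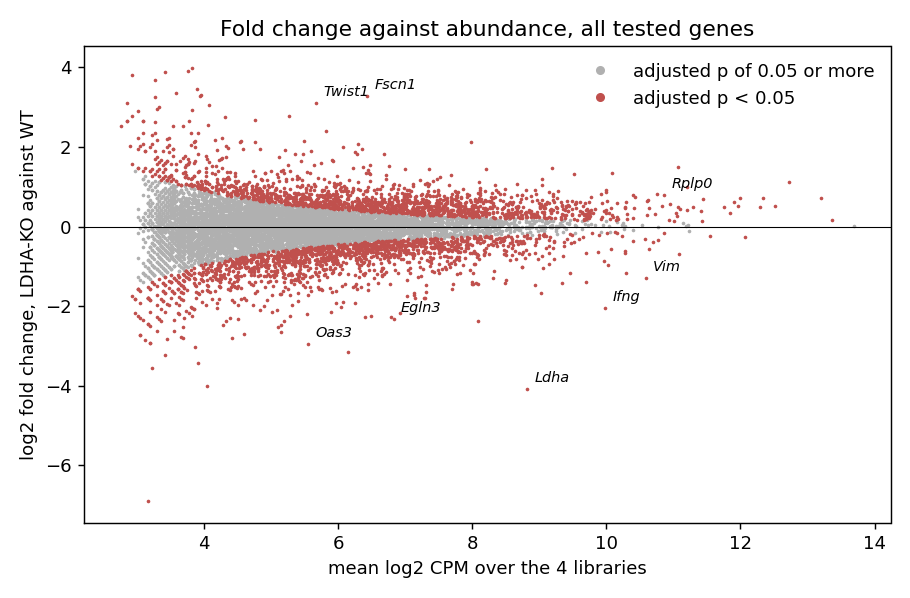
Log2 fold change of LDHA-KO against WT plotted against mean log2 CPM for the 9914 tested genes, with red points for an adjusted p under 0.05. Called genes lie on both sides of 0, 1549 above and 1527 below, and the fold changes spread widest at low abundance.

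The groups did not overlap for 6378 genes, 64.3% of those tested, where chance gives 33.3%. Without LDHA-KO replicate 2, 1973 genes were called, 1018 higher and 955 lower, and DESeq2 called 931, with 516 higher and 415 lower. Of the calls, 50.4% were higher with TMM scaling and 38.3% with library totals alone.

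Th1 effector genes fell as a group. Of 24 tested members, 12 fell and 2 rose (13 and 2 adjusted over the list alone), with a median log2 fold change of -0.47 (camera adjusted p = 1.04e-06). With an estimated correlation, a setting in which camera called 0 lists, the adjusted p was 0.213. Besides Ifng, the falls included Lta, the lymphotoxin alpha gene (111 ± 2.03 to 29.2 ± 0.238 CPM, log2 fold change -1.92), and the chemokine gene Ccl3 (234 ± 10.9 to 109 ± 16.6 CPM, -1.08), at edgeR adjusted p = 2.32e-11 and 6.22e-10. Il12rb2, a subunit of the IL-12 receptor, fell by 0.83 on the log2 scale (SE 0.12, edgeR adjusted p = 3.25e-07), and Gzmb, which encodes granzyme B, fell by 0.65 (SE 0.13, edgeR adjusted p = 0.000181). The chemokine receptor gene Cxcr3 fell by 1.35 (SE 0.39, edgeR adjusted p = 0.00657), with 5 and 10 counts in LDHA-KO.

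The Th1 master regulator gene Tbx21 had a log2 fold change of -0.27 (SE 0.13, edgeR adjusted p = 0.113), and Stat4, which encodes the transcription factor downstream of IL-12, had -0.34 (SE 0.19, adjusted p = 0.160). The values were -0.33 for Tnf (SE 0.13, adjusted p = 0.0504) and 0.09 for Il2 (SE 0.07, adjusted p = 0.388), so these 4 genes did not pass the test. With library totals alone Tbx21 (-0.35, adjusted p = 0.0354) and Tnf (-0.41, adjusted p = 0.0136) were called lower. The rises on the Th1 list were Bhlhe40 (0.34) and Runx3 (0.32), which encode transcription factors. Cxcr3 lost its call without WT replicate 1 (-1.28) and without LDHA-KO replicate 1 (-1.09). Lta overlaps Mir6974, Ccl3 overlaps Ccl4, Il12rb2 overlaps Serbp1 and Stat4 overlaps 2 gene models.

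The list of cytokine and chemokine genes, which shares members with the Th1 list and so partly repeats its result, held more falls than rises. Of 25 tested, 15 fell and 5 rose (17 and 6 adjusted over the list alone), with a median of -0.45 (camera adjusted p = 1.90e-07; adjusted p = 0.213 with an estimated correlation). Tnfsf8, which encodes the CD30 ligand, fell from 362 ± 18.9 to 133 ± 8.04 CPM (log2 fold change -1.43, edgeR adjusted p = 3.18e-15). The risers were Tnfsf10 (2.96), the TRAIL gene, Cxcl10 (1.01), Tnfsf9 (0.96), Tnfsf14 (0.77) and Mif (0.44). Ifng, Lta and Ccl3 stand on this list and on the Th1 list.

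Type I interferon response genes showed the lowest median of the lists tested, -1.15. Of 27 tested, 17 fell and 1 rose (19 and 1 adjusted over the list alone; camera adjusted p = 8.81e-06; adjusted p = 0.271 with an estimated correlation). Oas3 fell from 73.6 ± 11.1 to 9.37 ± 0.454 CPM (SD, n = 2 each, edgeR adjusted p = 6.13e-12), Trim30a fell by 2.26 on the log2 scale (adjusted p = 4.09e-09) and Parp14 fell by 1.72 (adjusted p = 9.18e-08). Gbp2, a guanylate-binding protein gene induced by interferons, was the riser (270 ± 48.1 to 560 ± 13.5 CPM, log2 fold change 1.06, edgeR adjusted p = 3.17e-13). Gbp2 overlaps Mir6381 and Trim30a overlaps Gm25405.

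Glycolysis genes other than Ldha rose. Of 21 tested, 9 rose and 0 fell, also when adjusted over the list alone, with a median log2 fold change of 0.47 (camera adjusted p = 7.64e-06; adjusted p = 0.440 with an estimated correlation; adjusted p = 0.0505 by fry). Slc2a3, which encodes the glucose transporter GLUT3, rose from 28.1 ± 5.05 to 113 ± 7.18 CPM (log2 fold change 2.00, SE 0.18, edgeR adjusted p = 8.93e-12). Gpi1, Aldoa and Pkm, which encode glycolytic enzymes, rose by 0.85, 0.47 and 0.43 on the log2 scale (edgeR adjusted p = 1.20e-10, 3.25e-09 and 4.97e-09). Gapdh had 13 to 26 counts per library and has near-identical pseudogene copies, so its count is uncertain.

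Sterol and fatty acid synthesis genes also rose, 13 of 30 tested with 0 lower (14 and 0 adjusted over the list alone), with a median of 0.45 (camera adjusted p = 4.31e-05; adjusted p = 0.213 with an estimated correlation). Hmgcs1, which encodes an enzyme of the mevalonate pathway, rose by 1.34 (edgeR adjusted p = 3.17e-09) and the desaturase gene Scd2 by 0.84 (adjusted p = 6.12e-10). Acly, which encodes the enzyme that makes cytosolic acetyl-CoA from citrate, fell from 629 ± 16.8 to 357 ± 2.39 CPM (SD, n = 2 each, log2 fold change -0.82, SE 0.07, edgeR adjusted p = 6.16e-12). On the list of acetyl-CoA supply and histone acetylation genes, which was not called (camera adjusted p = 0.629), 7 of 30 rose and 2 fell, the same counts as when adjusted over the list alone. Over all tested genes 3076 of 9914 were called, a similar share, so these counts show no change particular to this list. Its risers included Hdac7 (0.70), a histone deacetylase gene, Kat2a (0.74), an acetyltransferase gene, and Brd2 (0.37), whose protein binds acetylated histones, with edgeR adjusted p = 6.36e-08, 0.00409 and 0.00118. Kat2a and Brd2 were not called by DESeq2. Hdac7 overlaps Slc48a1 and Brd2 overlaps H2-DMa.

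The 7 tested genes of the mitochondrial genome all rose, also when adjusted over the list alone (median 0.79, camera adjusted p = 2.54e-09). With the estimated correlation, 0.982, camera's adjusted p was 0.361, and fry did not call the list (adjusted p = 0.0930). At such a correlation these genes are far from independent, so the p-value at the preset 0.01 overstates the evidence. mt-Nd6 rose most, from 625 ± 87.1 to 1574 ± 142 CPM (log2 fold change 1.34, edgeR adjusted p = 1.00e-19), with mt-Nd1 at 1.04, mt-Co1 at 0.92 and mt-Cytb at 0.68. mt-Nd6, encoded on the opposite strand to the other protein-coding genes of the mitochondrial genome, held 3.72 to 6.21 times the counts of mt-Cytb in each library. The nuclear genes of oxidative phosphorylation were not called as a list by camera (median 0.20, adjusted p = 0.141) but were by fry (0.0324) and by camera with no filter on low counts (0.0219), with 10 of 66 higher and 1 lower (4 and 0 adjusted over the list alone). Cox6c (0.93), Atp5c1 (0.67), Cox7a2l (0.68) and Atp5b (0.20) were among those higher; Cox7a2l, Atp5c1 and Atp5b were not called by DESeq2. Atp5b lost its call without WT replicate 1 (0.16) and with library totals alone (0.12), Atp5c1 without LDHA-KO replicate 2 (0.45), and Cox7a2l without WT replicate 1 (0.59) or LDHA-KO replicate 1 (0.57).

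Neither the tricarboxylic acid cycle list, the HIF-1 target list nor the list of pentose phosphate, serine and one-carbon genes was called (camera adjusted p = 0.486, 0.772 and 0.772), and each held members that changed in both directions. Of 31 tricarboxylic acid cycle genes, 8 rose and 6 fell (9 and 6 adjusted over the list alone), among them Glud1 (-0.70), Pdp1 (-2.30), Ogdh (0.75) and Pdha1 (0.59). Of 24 HIF-1 targets, 7 rose and 4 fell (9 and 4 adjusted over the list alone). Egln3, a prolyl hydroxylase gene induced in hypoxia, fell from 175 ± 0.331 to 34.7 ± 0.500 CPM (log2 fold change -2.33, edgeR adjusted p = 9.82e-16), and Ndrg1 fell by 0.65, while Adm rose by 2.00 and Egln1 by 0.61. Hif1a itself fell by 0.40 (SE 0.08, edgeR adjusted p = 9.33e-05). Of 23 pentose phosphate, serine and one-carbon genes, 5 rose and 3 fell (6 and 3 adjusted over the list alone), including Mat2a (-1.07), Mthfd1 (0.62), Mthfd1l (0.53) and Tkt (0.36). Mthfd1 and Mthfd1l were not called by DESeq2.

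Unfolded protein response genes fell: 13 of 25 were lower and 1 was higher (16 and 1 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 1.73e-06; adjusted p = 0.213 with an estimated correlation). Xbp1, which encodes a transcription factor of this response, fell from 195 ± 11.1 to 81.6 ± 0.346 CPM (log2 fold change -1.26, edgeR adjusted p = 1.10e-10). The chaperone genes Hspa5, Pdia6 and Hyou1 fell by 0.66, 1.11 and 0.87 (edgeR adjusted p = 3.74e-11, 8.39e-10 and 8.49e-09), and P4hb rose (0.52). Hspa5 overlaps Rabepk and Pdia6 overlaps Atp6v1c2. Genes of ATF4 and the integrated stress response fell in 17 of 31 cases and rose in 2 (18 and 3 adjusted over the list alone), with a median of -0.44 (camera adjusted p = 0.000540; adjusted p = 0.213 with an estimated correlation). The amino acid transporter gene Slc7a5 fell by 0.69 (edgeR adjusted p = 3.96e-08) and the tRNA synthetase gene Gars by 0.59 (adjusted p = 1.79e-06), whereas Slc3a2, which encodes the partner chain of the Slc7a5 protein, rose by 0.59 (adjusted p = 4.08e-06) and Sesn2 by 0.69 (adjusted p = 7.43e-06).

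Cytosolic ribosomal protein genes rose in 46 of 63 cases with 0 lower (53 and 0 adjusted over the list alone), with a median of 0.53 (camera adjusted p = 8.89e-20; adjusted p = 0.213 with an estimated correlation). Rplp0 rose from 1372 ± 11.5 to 2375 ± 63.3 CPM (log2 fold change 0.79, edgeR adjusted p = 4.14e-16), and Rpl13a, Rplp1 and Rps26 rose by 0.86, 0.81 and 0.66. These genes have many processed pseudogenes, which makes their counts uncertain. MYC and ribosome biogenesis genes were not called as a list by camera (median 0.19, adjusted p = 0.130) but were by fry (0.0237) and by camera with no filter on low counts (0.0219), with 12 of 40 higher and 2 lower (13 and 2 adjusted over the list alone). Ncl rose by 0.45, Npm1 by 0.49 and Ppan by 0.45, while Odc1, of polyamine synthesis, fell by 0.69. Myc rose by 0.23 (SE 0.08, edgeR adjusted p = 0.0283). Myc lost its call with library totals alone (0.15), in DESeq2 (0.23), with the filter of CPM above 1 (0.23), after thinning (0.21), without WT replicate 1 (0.20) and without LDHA-KO replicate 2 (0.06), and stood at 0.38 without LDHA-KO replicate 1.

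T cell activation genes were called higher with a small median, 0.09 (camera adjusted p = 0.0144; adjusted p = 0.271 with an estimated correlation), and 13 of 36 rose while 8 fell (13 and 10 adjusted over the list alone). The immediate early genes Egr1, Egr2 and Jun rose by 1.11, 1.86 and 1.45 (edgeR adjusted p = 3.95e-13, 1.03e-11 and 1.45e-16), and Nfkbia, an inhibitor of NF-kappaB, from 327 ± 0.645 to 745 ± 23.9 CPM (log2 fold change 1.19, adjusted p = 4.33e-17). The fallers included Dusp5 (-0.70), Cd44 (-0.37), Fosl1 (-0.62) and Fosb (-0.72). The list was not called when no filter on low counts was used.

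**Figure D3:**
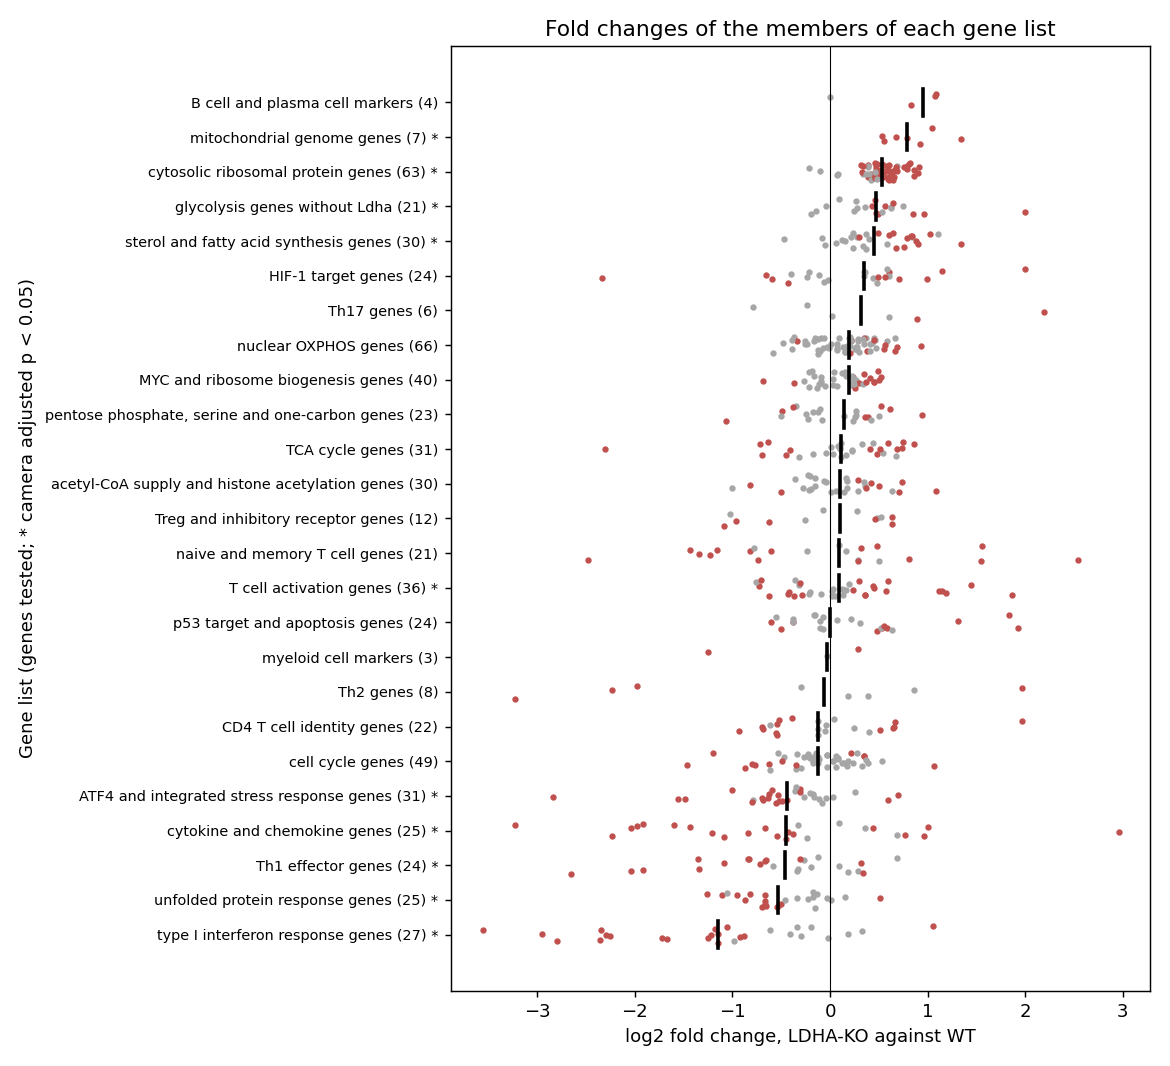
Log2 fold changes of LDHA-KO against WT for the tested members of 25 gene lists, with a point per gene, red for an adjusted p under 0.05, a black bar for the list's median, and a star for lists called by camera. Type I interferon response genes lie furthest below 0 by median (-1.15), and cytosolic ribosomal protein genes cluster around 0.53.

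Camera called 10 of the 25 lists tested, 5 higher and 5 lower. Counts of changed list members stand against 3076 called of 9914 tested genes, 1549 higher and 1527 lower. With an estimated correlation, camera called 0, with 5 at an unadjusted p under 0.05, and fry, which tests each list by itself, called 13.

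Genes of other T helper states were not called as lists by camera, while fry called Th2 genes lower. Of 8 tested Th2 genes, 1 rose and 3 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.377; adjusted p = 0.0267 by fry). Gata3, the Th2 regulator gene, rose from 8.18 ± 0.740 to 31.9 ± 3.50 CPM (log2 fold change 1.96, edgeR adjusted p = 6.14e-06), while the cytokine genes Il3 (-1.98) and Il10 (-2.24) fell, as did Il24. Il10 had 1 and 7 counts in LDHA-KO, and its fitted value of -3.94 without LDHA-KO replicate 2 rests on 1 count, a ratio of 16.9 (95% counting interval 2.89 to 679). Of 6 Th17 genes, Batf (0.89) and Ahr (2.19) rose and 0 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.377). Ahr lost its call without LDHA-KO replicate 1 (1.69).

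Of 12 Treg and inhibitory receptor genes, 3 rose and 3 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.344). Il2ra, which encodes the IL-2 receptor alpha chain, fell from 1356 ± 22.7 to 696 ± 48.2 CPM (log2 fold change -0.97, edgeR adjusted p = 1.54e-16), Ctla4 fell by 1.09 and Tnfrsf4 by 0.62, and Tnfrsf18 rose by 0.64. This list's median was 0.10, its mean -0.08 and its test direction lower. Naive and memory T cell genes likewise had a median of 0.09, a mean of -0.11 and a test direction of lower (camera adjusted p = 0.248; adjusted p = 0.0132 by fry, called), with 7 of 21 higher and 8 lower, also when adjusted over the list alone. Satb1 (-0.82), Bcl2 (-1.43) and the homing receptor gene Ccr7 (-0.74) fell and Igfbp4 (1.54) rose. Of 22 CD4 T cell identity genes, 5 rose and 8 fell (6 and 9 adjusted over the list alone; camera adjusted p = 0.323; adjusted p = 0.0227 by fry, called lower), among them Cd2 (-0.94), Cd247 (-0.54) and Zap70 (0.67).

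Cell cycle genes were not called (camera adjusted p = 0.486), with 4 of 49 higher and 8 lower (3 and 8 adjusted over the list alone). E2f2 (-1.20) and Rrm2 (-0.63) fell, and Ccna2 (0.35) and Bub1 (1.06) rose. Of 24 p53 target and apoptosis genes, 7 rose and 3 fell, also when adjusted over the list alone (camera adjusted p = 0.357). The proapoptotic gene Bcl2l11, which encodes BIM, rose from 15.5 ± 1.84 to 60.5 ± 12.0 CPM (log2 fold change 1.93, edgeR adjusted p = 2.69e-08), with Phlda3 at 1.83, Fas at 1.31 and Ccng1 at 0.53. Bcl2l11 overlaps Acoxl, and DESeq2 did not call Rrm2, Ccna2, Bub1 or Ccng1.

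Of 91 markers of other cell types, 50 had 0 counts in LDHA-KO, and the most abundant, Csf1r, stood above the median of CD4 T cell identity genes there (400 against 171 CPM). Of the B cell and plasma cell markers, 4 could be tested and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.179). H2-Ab1 rose from 20.6 ± 1.03 to 42.9 ± 12.8 CPM, Cd74 from 22.2 ± 0.0345 to 38.9 ± 8.57 CPM and Ighm from 8.12 ± 3.66 to 17.2 ± 1.88 CPM (edgeR adjusted p = 0.000690, 0.00807 and 0.0320). Without LDHA-KO replicate 2 these 3 genes lost their calls (log2 fold changes 0.72, 0.57 and 0.95), and DESeq2 called neither H2-Ab1 nor Cd74. Ighm also lost its call without LDHA-KO replicate 1 (1.18), without WT replicate 2 (0.69) with library totals alone (0.99) and with the filter of CPM above 1 (1.07), and stood at 1.62 without WT replicate 1. Of 3 tested myeloid markers, Csf1r rose from 328 ± 1.73 to 400 ± 9.45 CPM and Xcr1 fell from 21.4 ± 1.15 to 8.93 ± 0.169 CPM, also when adjusted over the list alone (edgeR adjusted p = 0.00500 and 0.00599; camera adjusted p = 0.965). Both lost their calls without LDHA-KO replicate 2 (0.27 and -1.22), and DESeq2 did not call Csf1r. No marker of NK, CD8 or gamma-delta T cells could be tested, the highest count in any library being 8, for Cd8b1. The lists of erythroid, platelet and stromal markers and of replication-dependent histone genes had 2 tested members each, with highest counts of 21 for Alas2 and 18 for Hist1h1c.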

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

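The test on genes that overlap no other RefSeq gene and the thinning of libraries were chosen after the result was seen. Ldha and Ifng were called lower under each alternative run on them; Ldha overlaps a gene model and so has no value among non-overlapping genes. The count of changed genes, 3076, ranged from 1973 to 2412 with a library left out, where the lone library is assumed to vary like the other genotype (1018 to 1231 higher, 955 to 1208 lower). DESeq2 called 931 (516 higher, 415 lower), none in the opposite direction. It gave a median fitted dispersion of 0.0632 against edgeR's trended 0.00128, and no adjusted p for 3183 of edgeR's genes; 1581 of 2512 edgeR calls with a DESeq2 adjusted p were lost. Non-overlapping genes gave 1255 calls (633 higher, 622 lower) among 4550, fewer by construction, and a minimum 2-fold change left 842. The other alternatives gave 2586 to 3082 calls. With replicate numbers as a block, 2803 genes were called, 2792 of them shared; libraries of equal number did not deviate together (correlation -0.028), and no list or named gene changed its call. Camera with an estimated correlation called 0 lists, with adjusted p = 0.213 for Th1 effector genes (median -0.465) and 0.440 for glycolysis genes (median 0.472); fry gave the latter 0.0505. The estimated correlation lay below the preset 0.01 for Th1 effector (-0.038), unfolded protein response (-0.01), sterol (-0.016), ATF4 (-0.014) and T cell activation genes (-0.026). These values argue against a higher correlation as the cause of those lost calls. For the other lists that camera called, the estimate lay above 0.01, among them glycolysis genes (0.369) and mitochondrial genome genes (0.982). With an estimated correlation camera also uses only the residual degrees of freedom that 4 libraries leave, far fewer than with a preset correlation. For Th1 effector genes the unadjusted camera p went from 1.67e-07 to 0.0284 although the estimate was lower than the preset. The lost calls therefore cannot decide about single lists. Uncalled results that changed direction were Il2 without LDHA-KO replicate 2 (-0.002; range over left-out libraries -0.002 to 0.181) and the tests of 4 lists, given here with medians. For myeloid markers the test turned without WT replicate 1 (0.058), without LDHA-KO replicate 1 (0.225; range -0.412 to 0.225) and after thinning (-0.075). For pentose phosphate, serine and one-carbon genes it turned without LDHA-KO replicate 1 (-0.052; range -0.052 to 0.276) and among non-overlapping genes (-0.107), where it also turned for HIF-1 targets (0.378) and tricarboxylic acid cycle genes (0.096). Over all alternatives, named genes kept direction and call in 1415 cases, lost the call in 41 and gained it in 2; lists did so in 270, 13 and 7. DESeq2 gave no adjusted p for 25 of 119 named genes. The planned GC and length correction was not run. In the simulation, with these library sizes and 2 libraries per genotype, 36.5% of 1.5-fold changes were recovered. No other depth or replicate number was simulated, so this share cannot be put down to depth. There, 96 genes were changed 1.5-fold and 97 were changed 2-fold, against 3076 called in the data, so recovery in the data may differ.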

Other observations

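The tests of mt-Nd6 against mt-Cytb, of the spread of Th1 effector genes, of other-cell markers type by type, of genes that overlap no other gene and of thinned libraries were chosen after the result was seen, as were the genes named in the next paragraph and the neighbouring genes compared below.

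Outside the lists, genes of smallest p that overlap no other RefSeq gene included Vim, which encodes the intermediate filament protein vimentin and fell from 2151 ± 47.9 to 872 ± 61.6 CPM (SD, n = 2 each, log2 fold change -1.30, edgeR adjusted p = 6.96e-22). Ahnak, which encodes a large scaffold protein, fell from 502 ± 44.7 to 190 ± 5.33 CPM (log2 fold change -1.41, adjusted p = 1.75e-16), and Mettl14, a subunit of the RNA m6A methyltransferase, by 1.79 (adjusted p = 2.04e-14). Twist1, a transcription factor gene, rose from 11.3 ± 1.39 to 96.7 ± 4.00 CPM (log2 fold change 3.09, edgeR adjusted p = 1.38e-14). Tnfsf4, the OX40 ligand gene, rose by 1.44 (adjusted p = 1.45e-11), Eef1a1, a translation elongation factor gene, by 0.62 (adjusted p = 7.91e-15) and Hsp90ab1 by 0.51 (adjusted p = 2.38e-12).

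Some genes held more counts than their overlapping neighbours: over the 4 libraries Snx22 had 10654 counts and Ppib, which it overlaps, 517, and Phykpl had 48349 against 7404 for Hnrnpab. If reads had been counted on the strand opposite to the library's, antisense genes should outnumber their overlapping sense partners; they did in 38 of 74 overlapping pairs, 51.4% (exact binomial 95% interval 39.4% to 63.1%), and in 59 of 151 pairs, 39.1% (31.2% to 47.3%), once pairs that do not overlap, for which this is not predicted, are added. The test of pairs cannot decide, because correct counting predicted a share below 50% and the interval spans that value. No strand setting is given in the sources used. The neighbouring genes above and the high mt-Nd6 counts go with opposite-strand counting, but both were picked after the result was seen. Opposite-strand counting thus stays open. If it took place, the counts of genes that overlap no other, such as Ifng, would be antisense reads too. A library that keeps no strand stays open as well: mt-Nd6 had at least 3.72 times the counts of mt-Cytb in each library, but this ratio prompted the question, and 5 of the 13 protein-coding mitochondrial genes had 0 counts, so more than strand shapes these counts; no biological explanation was tested.

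The fall of Th1 effector genes was weighed against 3 technical explanations. Among the 15 members that overlap no other gene the list was still called lower (median -0.31, camera adjusted p = 6.69e-06). The median of all 24 members was -0.47, so this argues against reads of overlapping genes as the whole cause only. After thinning the median was -0.48 (camera adjusted p = 3.55e-06). This cannot decide on depth, because random thinning leaves the expected ratios between genotypes unchanged and TMM scaling was already in use. Dilution by other cells would lower the members by about the same factor, yet 12 of 24 lay over 3 standard errors from the list's median, with Ifng at -2.04 and Il2 at 0.09, which argues against it as the whole cause. Other cells would need 27.6% of the RNA, but the upper quartile of their 91 markers was 0.645% of the median of CD4 T cell identity genes, and by type at most 2.74% (B and plasma cells), with Csf1r alone at the needed level; a smaller share stays open, as H2-Ab1 (20.6 to 42.9 CPM), Cd74 (22.2 to 38.9) and Ighm (8.12 to 17.2) rose. An effect of LDHA loss on the Th1 programme stays open as a hypothesis. The list was fixed before the data were examined, but the effect was not tested on other data. With an estimated correlation the list's camera adjusted p was 0.213, although that estimate, -0.038, lay below the preset 0.01. That setting has few degrees of freedom with 4 libraries and called 0 lists, so it cannot decide about this list.

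The fall of interferon response genes also held among the 14 members that overlap no other gene (median -1.18, camera adjusted p = 7.99e-06). For the whole list, camera with an estimated correlation gave adjusted p = 0.271, in a setting that called 0 lists and so cannot decide. The value of non-overlapping members argues against reads of overlapping genes as the whole cause. An effect of LDHA loss on these genes stays open and was not tested further.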
